A study of Mus musculus with 81 samples.

How the data were processed

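RNA of whole hearts was profiled on 81 Affymetrix arrays, 1 per strain and diet. Per the labels' protocols, the RNA of about 5 fasted males of 29 weeks was pooled evenly before hybridisation, so the spread between animals is not seen in the values. Diet was taken from the treatment label, which matched the sample title on all 81 arrays. The protocol text shared by all samples describes chow alone, so it conflicts with the label of the high fat samples. Strain was taken from the genotype label.

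The deposited values are a score per probe set on a log-like scale, of which the authors' base and slope are not stated. Per the submitters' processing notes the arrays were handled with Affymetrix Expression Console, with no version named. The summarisation and background steps are not given in the sources used here. Tested on the values, each array has a mean of 8 and an SD of 2 over 41345 probe sets, with medians between 7.62 and 7.75. A rescaling of this kind removes differences between arrays in overall level and spread, and a shift shared by most transcripts cannot be seen in it. Because the scale is not known to be log2, differences are given in units, and no fold is printed. The plan assumed log2 values. Array signal sets no depth, and the number of arrays limits the precision.

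Probe sets were named through the platform's gene table. It holds 25335 of the probe sets, of which 23521 have 1 gene symbol and 1814 several, and none was named from the latter. The other 16010 probe sets are unnamed here, 190 of them controls. For each of 22180 genes the probe set with the highest mean over all arrays was used. Of the genes' Entrez identifiers 21994 were found in a RefSeq gene table (assembly GRCm38.p6) with 0 differing symbols. That table was used for names and for which genes neighbour each other, and no coordinates are printed since the array's build is not given in the sources used here. No filter on level was applied.

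Differences between the diets were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) on the 78 arrays of the 39 paired strains, with strain and diet as terms and Benjamini-Hochberg adjustment. The pairing comes from the strain labels. The deviations of a strain's chow and high fat arrays from the diet means correlated with a median r of 0.248, against -0.00927 for arrays of different strains. For 31 of 39 strains the own high fat array was the best match, and 37 had an r over 0.1. Strain was tested with limma's F test in the same model, with the intraclass correlation of the 2 arrays of a strain as its size. Parents were compared as a contrast of that model.

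A set of 45 gene lists of pathways, stress responses and cell types was fixed before the data were examined, with 760 of 839 listed genes measured. Listed genes that are not measured were not analysed here. The mean difference of a list's members was taken in each strain and tested by flipping signs over strains (100000 draws, two-sided), and by limma's camera with a preset correlation of 0.01 and with an estimated one. List means and their 95% intervals between strains were also set against 10000 random lists matched on level. Genes are named by a rule fixed beforehand. For diet it takes the 12 largest rises and 12 largest falls at an adjusted p under 0.05 with the same direction in at least 30 strains, and up to 4 members with the smallest adjusted p of each list described. For strain it takes the 12 highest intraclass correlations among called genes above the median level and all genes on the list of known variants, and for the parents the 8 largest differences in each direction. Predicted genes, olfactory and vomeronasal receptors and microRNAs are counted but not named. A further set from the brighter genes was chosen after the data were seen.

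The tests were also run on simulated data. Of 100 genes given a shift of 0.2 units in the diet comparison 74 were called, and of 100 given 0.4 units 99, while 9 of 21980 unchanged genes were called. Of 2000 genes given strain variation 1643 were called, against 79 of 20180 without. The simulated genes varied independently of each other, and no technical difference between the chow and high fat arrays was put in. The counts of false calls therefore do not cover correlated genes or such a difference. Alternatives covered the strain term, variance model, array weights (with statmod 1.5.0), quantile and median scaling, dim genes, the probe set per gene, the strains included and covariates. They were planned beforehand, except the removal of 3 strains, the size of the control probe sets' differences and the tissue marker covariates. A minimum fold of change had been foreseen as well and could not be applied without a known scale.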

Results

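Transcript levels were measured in whole hearts of male mice from the BXD family, a set of recombinant inbred strains derived from crosses of C57BL/6J with DBA/2J, and from both parent strains. The animals were 29 weeks old and had been fasted overnight. Each of the 81 arrays was hybridised with a pool of RNA from about 5 animals of 1 strain on 1 diet, 42 pools from chow and 39 from a high fat diet. The composition of the high fat diet is not given in the sources used here. Both diets were represented for 39 strains (37 BXD strains and both parents), and 3 further BXD strains had a chow array alone. With 1 array per strain and diet, the strains served as replicates for the diet comparison, and the number of arrays limits the precision. Values are in rescaled expression units, set so that every array has a mean of 8 and an SD of 2 over its probe sets. One unit is therefore 0.5 of an array's SD and cannot be read as a doubling, because the scale is not known. Pairs of arrays correlated over 22180 genes with r between 0.969 and 0.992, so no array was a copy of another.

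The first comparison asked which transcripts differed between the diets within strains. Genes for the breakdown of branched chain amino acids (leucine, isoleucine and valine) fell together on the high fat diet. Of 19 measured members 15 fell, 0 rose and 4 did not pass the test, and the counts were the same when adjusted over the list alone. Bckdhb, a subunit of the branched chain ketoacid dehydrogenase, went from 12.1 ± 0.292 on chow to 11.7 ± 0.270 on high fat (SD, n = 39 strains), a difference of -0.435 ± 0.0321 (SE) that was negative in 38 of 39 strains (adjusted p = 1.64e-14, limma). Ppm1k, the phosphatase that activates this dehydrogenase, differed by -0.375 ± 0.0389 (SE). Acadsb and Ivd, acyl-CoA dehydrogenases of the isoleucine and leucine routes, differed by -0.335 and -0.311, each lower in 38 of 39 strains. The mean of the list fell by 0.175 ± 0.111 (SD between strains, 95% interval -0.211 to -0.139) and was lower in 38 strains (sign-flip permutation test, two-sided, adjusted p = 0.00015, from the smallest p that the permutations can give, 1e-05). The list also stood apart from other genes in camera's test with a preset correlation (adjusted p = 1.47e-08), but not with an estimated correlation (adjusted p = 0.40).

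The list means of genes for the use of ketone bodies and for contraction were lower as well. Of 5 measured ketone genes 3 fell and 1 rose. Oxct1, the transferase that activates acetoacetate, fell by 0.268 ± 0.0279 (SE) and was lower in 38 of 39 strains, and Bdh1, the 3-hydroxybutyrate dehydrogenase, fell by 0.263 ± 0.0457. The list mean fell by 0.121 ± 0.107 (SD) and was lower in 34 strains (adjusted p = 0.00015), but camera did not call it (adjusted p = 0.318 with the preset and 0.995 with an estimated correlation). Of 24 sarcomere and contraction genes 14 fell and 0 rose, with a list mean of -0.0705 ± 0.0934 (SD), lower in 29 strains (adjusted p = 0.00072). Myom2, an M-band protein, fell by 0.431 ± 0.0427 (SE), Mylk3, the cardiac myosin light chain kinase, by 0.161, Myl3, the ventricular essential light chain, by 0.148 and Tnnc1, cardiac troponin C, by 0.118. The sarcomere list passed camera's test with the preset correlation (adjusted p = 0.0138) and missed it with an estimated one (adjusted p = 0.995). Transcriptional regulators of energy metabolism had a lower mean of -0.0278 ± 0.0486 (SD), lower in 29 strains (adjusted p = 0.00401), with 7 of 26 lower and 1 higher (5 lower when adjusted over the list alone), but it missed the test with each array centred on its median (adjusted p = 0.206). Camera did not call it either (adjusted p = 0.409 with the preset and 0.995 with an estimated correlation). Esrrg, an oestrogen-related receptor, fell by 0.150, and Ppara, the fatty acid receptor, rose by 0.178. Adjusted over the list alone, the counts of the ketone and sarcomere lists were the same.

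The means of matrix genes and of marker lists for several cell types other than cardiomyocytes were higher on high fat. Of 28 collagen and matrix genes 17 rose and 0 fell. Sparc, a matrix glycoprotein, rose by 0.247 ± 0.0275 (SE) and was higher in 35 of 39 strains (adjusted p = 9.86e-10, limma). Col6a2, Col6a3 and Col15a1, collagen chains, rose by 0.261, 0.249 and 0.302. The list mean rose by 0.130 ± 0.176 (SD, 95% interval 0.0725 to 0.187) and was higher in 30 strains (adjusted p = 0.00075), and camera's adjusted p was 0.0006 with the preset correlation and 0.995 with an estimated one. Of 17 macrophage markers 8 rose and 0 fell, with a list mean of 0.113 ± 0.179 (SD), higher in 24 strains (adjusted p = 0.00175). Ccr2, a chemokine receptor of monocytes, rose by 0.439 ± 0.0438 (SE), Cd68 by 0.234 and Itgam by 0.266. Camera's adjusted p for this list was 0.047 with the preset correlation and 0.995 with an estimated one. Mesothelial markers, genes of the outer lining of the heart, rose in 6 of 9 cases, with a list mean of 0.187 ± 0.301 (SD), higher in 27 strains (adjusted p = 0.00175). Camera did not call this list (adjusted p = 0.0551 with the preset and 0.995 with an estimated correlation). Calb2 rose by 0.312, Krt8 by 0.272 and Wt1 by 0.165. The fibroblast marker mean was 0.0698 ± 0.161 (SD), higher in 28 strains (adjusted p = 0.0265), and the endothelial marker mean was 0.0428 ± 0.0799, higher in 28 strains (adjusted p = 0.00649). Camera called neither (adjusted p = 0.350 and 0.517 with the preset correlation, and 0.995 for both with an estimated one). Of 11 fibroblast markers 4 rose and 0 fell, and of 13 endothelial markers 3 rose and 1 fell. Over all genes 45.0% were called in either direction, a share to set beside the counts of every list. The fibroblast and endothelial lists lie below this share, and the macrophage list lies near it. The counts of the collagen, macrophage, mesothelial, fibroblast and endothelial lists were the same when adjusted over the list alone. The call for the fibroblast markers was lost in a comparison of all 42 chow with all 39 high fat arrays that left out the strain block (adjusted p = 0.211).

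The shifts of several of these lists moved with that of the atrial markers across the 39 strains, a relation computed after the data were seen for 44 lists. It was closest for the mesothelial markers (Pearson r = 0.807, Spearman rho = 0.802, each with permutation p = 1e-05, the smallest the permutations can give, and adjusted p = 0.000147 and 0.00011). Within each diet the levels of both lists had r of 0.743 on chow and 0.757 on high fat, and r of the shifts was 0.781 without BXD63 and BXD80, the strains with the most extreme atrial shifts. For fibroblast markers, collagen genes and macrophage markers r was 0.632, 0.544 and 0.525 (p = 3e-05, 0.0004 and 0.00041, adjusted p = 0.000264, 0.00225 and 0.00225). Their rho was 0.695, 0.599 and 0.533 (p = 1e-05, 6e-05 and 0.00038, adjusted p = 0.00011, 0.000528 and 0.00186). Without the same strains their r was 0.570, 0.496 and 0.578, and within diets it was 0.474, 0.411 and 0.264 on chow and 0.522, 0.481 and 0.421 on high fat. The branched chain list had r of -0.394 (p = 0.0114, adjusted p = 0.0314) and rho of -0.567 (p = 0.00019, adjusted p = 0.00104), with r of -0.293 without the same strains and -0.306 and -0.447 within the diets. Of the 19 called lists 8 showed such a relation, and of all 44 lists 18 did, 10 with a positive and 8 with a negative r. Lists not called between the diets were among them, such as cartilage and valve markers (r = 0.719) and adipocyte markers (r = 0.716). The relation is therefore not particular to lists that shifted with diet. With atrial and liver marker means as covariates the mesothelial shift was 0.156 (95% interval 0.0958 to 0.216), that of the fibroblast markers 0.0574 (0.0153 to 0.0995) and that of the macrophage markers 0.0999 (0.0488 to 0.151).

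**Figure D1:**
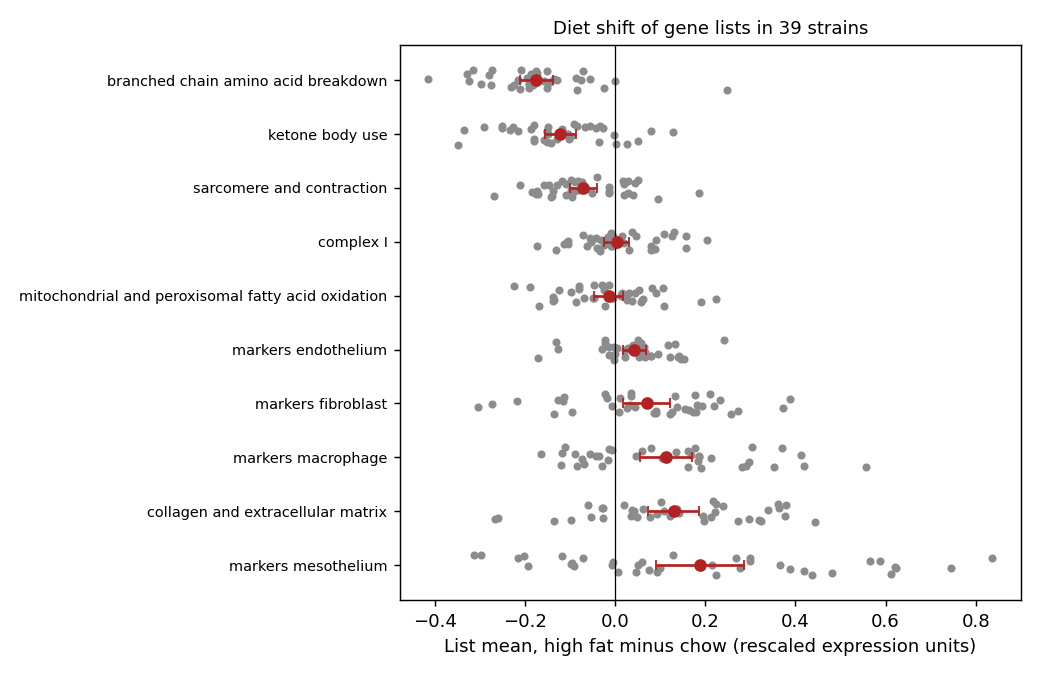
Difference of the list mean between high fat and chow, in rescaled expression units (horizontal axis), for 10 gene lists (vertical axis). Grey points are the 39 strains, spread vertically for display, and red points with bars are the mean and its 95% interval. The branched chain list lies below 0 in 38 strains, with a mean of -0.175, while the collagen list has a mean of 0.130.

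Other lists with a higher mean were angiogenesis and hypoxia (0.0652, 31 strains, adjusted p = 0.000225), endoplasmic reticulum stress (0.0507, 30 strains, adjusted p = 0.00175) and interferon response (0.10, 29 strains, adjusted p = 0.0158). The last was lost in the comparison of all 81 arrays without the strain block (adjusted p = 0.220), and 10 of its 26 members rose and 2 fell, or 10 and 3 when adjusted over the list alone. Egln3, a hypoxia-inducible prolyl hydroxylase, rose by 0.413, Atf5, a stress-responsive transcription factor, by 0.389 in 39 of 39 strains, and Rtp4, an interferon-induced gene, by 0.332. Markers of lung and of skeletal muscle also had higher means, of 0.0876 and 0.0461 (adjusted p = 0.00141 and 0.0134). The lung mean turned to -0.053 (adjusted p = 0.374) with members above the median gene level, and the skeletal muscle call was lost with such members (adjusted p = 0.146) and with the median over members (adjusted p = 0.438). Lower means were found for erythroid markers (-0.252 over 3 genes, lower in 36 strains, adjusted p = 0.00015), B cell markers (-0.112, adjusted p = 0.0091), thymus and T cell markers (-0.0566, adjusted p = 0.0434), fatty acid synthesis (-0.0562, adjusted p = 0.0365) and mitochondrial chaperones and proteases (-0.0436, adjusted p = 0.0244). The B cell and T cell calls were lost with members above the median gene level (adjusted p = 0.537 and 0.507), the latter also after quantile normalization (adjusted p = 0.0692), and the chaperone call with each array centred on its median (adjusted p = 0.141). The chaperone and fatty acid synthesis calls were also lost with the median over members (sign-flip adjusted p = 0.0658 for each). In all, 19 of 45 lists passed, 10 higher and 9 lower. Camera called 4 of them with the preset correlation and 0 with an estimated one, where 2 lists, the branched chain genes and erythroid markers, had an unadjusted p under 0.05. Among the 19 lists the adjusted p with an estimated correlation was 0.390 for erythroid markers, 0.40 for the branched chain genes and 0.995 for each of the others. Against level-matched random lists, endothelial, skeletal muscle, lung and endoplasmic reticulum stress means lay at percentiles 92.5, 88, 95.7 and 96.8. T cell, regulator, chaperone and B cell means lay at 15.2, 3.35, 3.05 and 2.75. These all lie within the central 95%. So did the interval bound nearer 0 for the mesothelial (95.4), macrophage (94.8), fibroblast (66.9) and interferon (82.7) lists. The same held for angiogenesis (91.6), ketone (4.18) and fatty acid synthesis (21.7). Removing a single strain ended the call for fatty acid synthesis in 15 of 39 cases (adjusted p up to 0.0649) and for thymus and T cell markers in 20 cases (adjusted p up to 0.0782).

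The other 26 lists did not pass, among them those for the oxidation of fat and for the respiratory chain. Of 27 fatty acid oxidation genes 6 rose and 6 fell, and the list mean was -0.014 ± 0.0981 (SD, adjusted p = 0.547). Decr1, a reductase for unsaturated fatty acids, rose by 0.232 and Cpt2, the inner carnitine palmitoyltransferase, by 0.172, while Hadhb, the beta subunit of the trifunctional protein, fell by 0.504. Among genes that respond to fatty acids through PPAR receptors, 3 of 20 rose and 4 fell (mean -0.0236 ± 0.243, adjusted p = 0.695). Lpl, lipoprotein lipase, fell by 0.182, and Slc25a20, the carnitine carrier, rose by 0.173. The complex I mean was 0.00377 ± 0.0867 over 33 genes (adjusted p = 0.842), with 7 higher and 8 lower. Within the glycolysis list, whose mean was 0.0114 (adjusted p = 0.547), Pfkfb2, Pfkl and Pfkp rose by 0.353, 0.263 and 0.288 and Eno3 fell by 0.195. Adipocyte markers had a mean of -0.0237 ± 0.365 (adjusted p = 0.833). Adipoq, which encodes adiponectin, was lower in 39 of 39 strains, Adig fell by 0.317, and Cidea and Cd36 rose by 0.276 and 0.0674. The mean of the tricarboxylic acid cycle was -0.0331 and that of complexes II to V -0.0256 (adjusted p = 0.0558 and 0.0942), and both passed after quantile normalization (adjusted p = 0.0157 and 0.0451). Cholesterol synthesis and uptake also passed after this normalization (-0.0303, sign-flip adjusted p = 0.0444). Insulin signalling passed with the median over members (-0.0286, sign-flip adjusted p = 0.0446).

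Over all 22180 genes 5288 were higher and 4697 lower on high fat at an adjusted p under 0.05 (limma with strain and diet in the model). The largest rises by the rule for named genes were those of Synpr (7.13 ± 0.181 to 8.02 ± 0.196, SD, n = 39), Spaca7, Tfrc, Obox3, Cd55, Sh2d2a, Hoxd1, Sv2b, Ankrd65, Hoxc4, Cenph and Pcdh9, between 0.895 and 0.591 units. The largest falls were those of Adipoq (7.52 ± 0.384 to 6.67 ± 0.230), Abat, Scgb1c1, Syt4, H2-Bl, Gdf3, Plcxd3, an immunoglobulin kappa variable gene, Tulp2, Nlrp1b, Snord52 and Pgbd1, between -0.852 and -0.605 units. Tfrc, the transferrin receptor, rose by 0.716 ± 0.117 (SE) in 32 of 39 strains, and Abat, the GABA transaminase, fell by 0.828 ± 0.0641 in 38. Of these 24 genes 21 lay below the median gene level of 8.18. A set from genes above that level was chosen by the same rule after the data were seen. In it Fcrls, Pla2g7 and Ube2l6 rose most after Tfrc, by 0.559, 0.510 and 0.481. After Abat and Scgb1c1 the largest falls were those of C7, Ccdc85b and Zfp1, by 0.579, 0.531 and 0.510. Smaller falls in the set included those of Cst3 and Myom2, by 0.432 and 0.431. Cst3, cystatin C, was lower in 39 of 39 strains.

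Spike-in control probe sets also differed between the diets, which limits what the gene count shows. Of 92 probe sets against ERCC spike-in sequences, which have no mouse target, 37 passed the same test over all probe sets (40.2%), 21 higher and 16 lower. The mean level of the 92 was 5.96, below the median gene level of 8.18. Among 4409 genes of the same level 45.1% passed it. The 95th percentile of the absolute difference of the ERCC probe sets was 0.247 units, and 2012 of the called genes differed by more. This limit comes from dim probe sets and was applied to genes of every level. Of 1394 olfactory and vomeronasal receptor genes, with a mean level of 5.99, 472 passed (33.9%). Their 95th percentile was 0.327, above the ERCC limit, and their largest absolute difference 0.856. Among dim genes a difference beyond the ERCC limit, or as large as those of most named genes, is therefore not set apart by its size. Of 75 other control probe sets, against bacterial and phage sequences and with a mean level of 9.03, 19 passed (25.3%), with a 95th percentile of 0.388, and of 23 background probe sets 6 passed (26.1%), with 0.0704. Differences of single genes between the diets are therefore not separated here from differences between the 2 sets of arrays, and no batch or date is given in the sources used here.

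**Figure D2:**
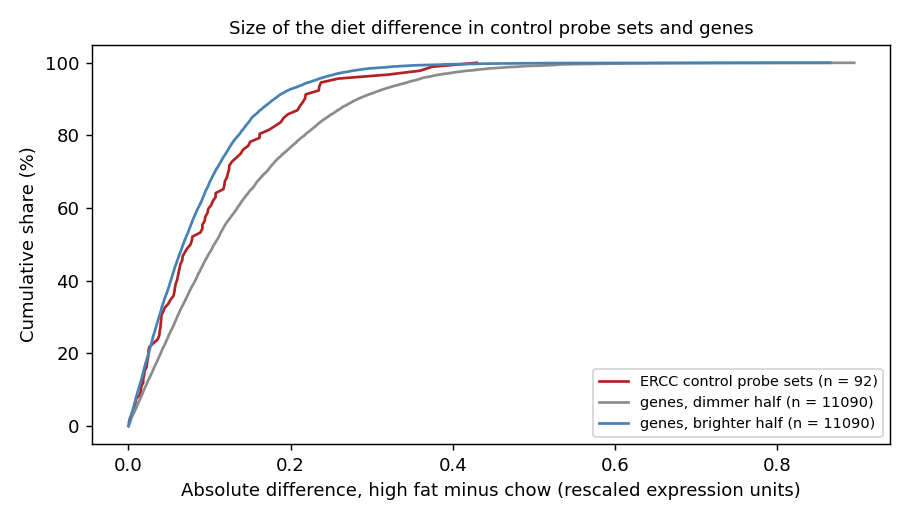
Cumulative share in percent (vertical axis) of 92 ERCC control probe sets, 11090 dimmer and 11090 brighter genes at or below an absolute diet difference in rescaled expression units (horizontal axis). The median is 0.0774 for the ERCC probe sets, 0.106 for the dimmer genes and 0.0674 for the brighter genes.

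The size of the difference between the diets varied moderately among strains. The root mean square difference over genes was lowest in BXD99 (0.267 units), had a median of 0.312 and was highest in BXD48 (0.431). The cosine of a strain's differences with the mean of the other strains ran from 0.286 in BXD68 to 0.491 in BXD99. These are values without a test, since a strain has 1 array per diet. In 3 relations fixed beforehand, the shift of the PPAR list was set against those of the circadian clock (Pearson r = 0.253, permutation p = 0.118; Spearman rho = 0.112, p = 0.497), adipocyte markers (r = -0.039, p = 0.813; rho = -0.00567, p = 0.973) and mitochondrial chaperones (r = 0.270, p = 0.0961; rho = 0.279, p = 0.0845) over 39 strains. None passed, with Benjamini-Hochberg adjusted p of 0.177, 0.813 and 0.177 for r and 0.745, 0.973 and 0.254 for rho. Without BXD68 and BXD69, the strains farthest from the median of the PPAR shift, r was -0.0111, 0.0509 and 0.178. The PPAR and adipocyte lists share 2 genes, without which r was -0.180.

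The second comparison asked which transcripts differed among strains. The list of genes with known C57BL/6J or DBA/2J variants, which was put together for strain differences, had the highest intraclass correlation of its mean between the 2 arrays of a strain, 0.943. Genes of antigen presentation, interferon response and cardiac stress followed among the fixed lists. The mean of the MHC class II list had an intraclass correlation of 0.818, with 9 of 12 members called, and that of the interferon list 0.720, with 22 of 26 called. The cardiac stress and fetal list had 0.635 with 16 of 19 called (each permutation p = 0.0001, the smallest the permutations can give, adjusted p = 0.000643 over 45 lists). Over all genes 3285 of 22180 differed among the 39 strains (limma F test, adjusted p under 0.05). Single genes were almost fixed by strain. H2-Ea, the alpha chain of the class II E molecule, had strain means from 6.49 in BXD71 to 13 in BXD80 and an intraclass correlation of 0.986 (adjusted p = 5.91e-32). This gene belongs to both the MHC class II list and the list of known variants, and their values without it were not computed. Kcnma1, a calcium-activated potassium channel, ran from 6.79 in BXD51 to 12.6 in BXD99 (0.982), and Cyfip2, a regulator of actin assembly, from 9.48 in BXD87 to 12.6 in BXD71 (0.981). Tnni3k, a kinase of cardiomyocytes, ran from 10 in BXD49 to 12.4 in BXD71 (0.958). Creg1, Pttg1, Art4, Fmn1, Pcp4l1, Sfi1, Fbxo44 and Polr1a had values between 0.949 and 0.982.

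Among 15 genes with known C57BL/6J or DBA/2J variants 10 differed among strains. Besides H2-Ea and Tnni3k these were Alad (intraclass correlation 0.923), Gpnmb (0.850), Myo5a (0.817), Glo1 (0.803), Nnt (0.620), Cdh23 (0.529), Ahr (0.510) and Klrd1 (0.388). The call for Klrd1 was lost with a variance trend and robust fit (adjusted p = 0.0516) and with tissue markers as covariates (adjusted p = 0.076). Hc (adjusted p = 0.0972), Gabra2 (0.102), Cox7a2l (0.166), Abcc6 (0.250) and Tyrp1 (0.346) did not pass, although Hc passed with the tissue covariates (adjusted p = 0.00606) and Gabra2 without BXD45, BXD48 and BXD96 (adjusted p = 0.0384).

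The third comparison set the parents against each other. Between DBA/2J and C57BL/6J, with 2 arrays each, 284 genes were higher in DBA/2J and 240 in C57BL/6J (limma on all 78 paired arrays, adjusted p under 0.05). H2-Ea, silenced in C57BL/6J by a promoter deletion, stood at 6.76 and 6.97 in C57BL/6J and at 10.5 and 11.4 in DBA/2J on chow and high fat, a difference of 4.07 ± 0.264 (SE, adjusted p = 2.29e-15, limma). Kcnma1 and Stab2, a scavenger receptor, were higher in DBA/2J by 3.99 and 3.13. Snord13, Snord53, LOC100861738 and the heat shock genes Hspa1a and Hspa1b were higher by between 2.54 and 3.93, and the call for Hspa1b was lost with a variance trend and robust fit (adjusted p = 0.0506) and with tissue markers as covariates (adjusted p = 0.0741). Among the BXD strains alone Hspa1b and Hspa1a were not called (limma F test, adjusted p = 0.250 and 0.0673). Of these strains 36 and 35 lay nearer C57BL/6J, so the difference of these 2 genes was not seen to segregate. Tnni3k, which carries a splice variant in DBA/2J, differed there by -2.04 ± 0.174 (adjusted p = 1.24e-11, limma), at 10.4 and 10.1 against 12.4 and 12.2. Mndal, Nxpe4, Trim12a, Rab6b, Cryzl2, Cyfip2 and Pttg1 differed by -2.94, -2.92, -2.81, -2.70, -2.51, -2.48 and -2.12. Alad and Glo1, genes with copy number gains in DBA/2J, were higher there by 1.21 and 0.682, and Myo5a by 0.768. Nnt, which has a deletion in C57BL/6J, did not differ between the parents here (0.152 ± 0.153, adjusted p = 0.762, limma). Leaving out 1 parent array, which assumes that the lone array varies like the other strains, gave 246 genes without the chow and 342 without the high fat array of C57BL/6J, and 274 and 283 without those of DBA/2J.

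Genes that differed between the parents also varied among the BXD strains. Of the 524 parent genes 396 (75.6%) were called among the 37 BXD strains alone, against 2376 of 21656 other genes (11%, Fisher's exact test p = 5.12e-251, with genes that are not independent). Both calls take their residual spread largely from the same BXD arrays. A gene with a small spread there passes either test more easily, so the 2 calls are not independent. The BXD means of several of them split into 2 ranges with the parents on opposite sides. For Tnni3k 14 strains lay at or below 10.8 and 23 at or above 12. For H2-Ea 24 strains lay at or below 7.20 and 13 at or above 10.4, for Cyfip2 16 and 21 lay on the 2 sides of a gap from 10.2 to 11.9, and for Alad 7 and 30 on the 2 sides of a gap from 12.7 to 13.6. In the same model 666 pairs of BXD strains differed by a median of 207.5 genes, with a range from 5 to 1161, and 20 pairs differed by at least as many genes as the parents.

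**Figure D3:**
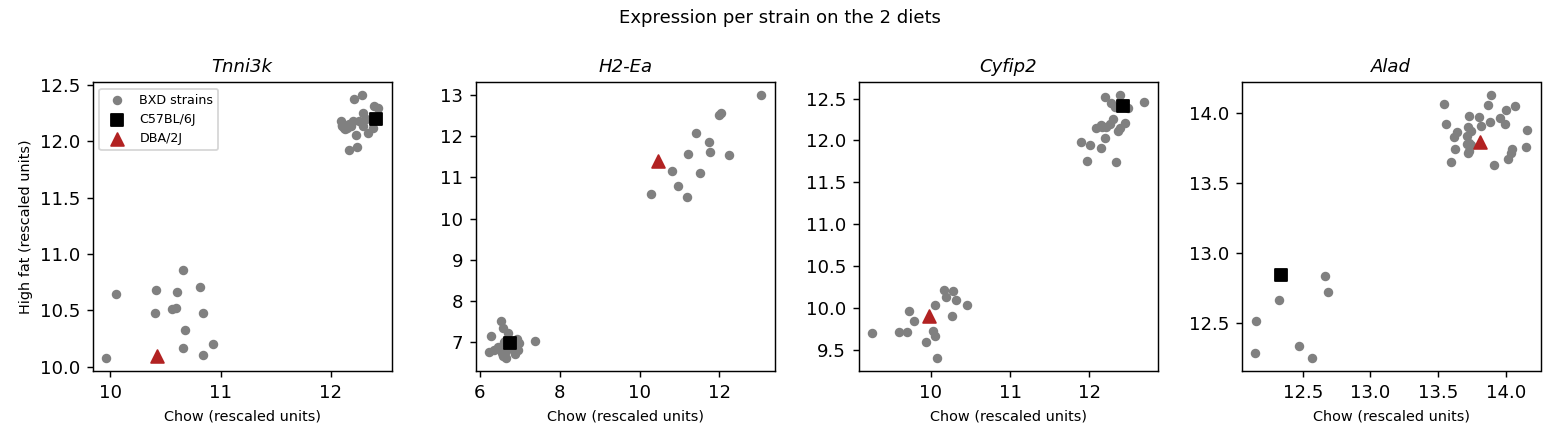
Expression in rescaled units on chow (horizontal axes) and on high fat (vertical axes) for Tnni3k, H2-Ea, Cyfip2 and Alad, with grey circles for the 37 BXD strains, a black square for C57BL/6J and a red triangle for DBA/2J. The strains form 2 separate sets in each panel, with 14 and 23 BXD strains for Tnni3k.

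Transcripts of atrium, liver and pancreas differed widely between pools. Myl7, the atrial regulatory light chain, ran from 6.66 on the chow array of BXD65 to 15.1 on the high fat array of BXD63, with medians of 13.5 on chow and 13.6 on high fat. The mean of 12 atrial markers differed by 0.129 ± 1.02 (SD) between the diets (adjusted p = 0.578). In DBA/2J it was 10 on chow and 11.7 on high fat, against 12.1 on both diets in C57BL/6J. Alb, serum albumin, reached 15.5 on the chow array of BXD96 against a median of 11.9, and Ctrb1, a pancreatic protease, 15.2 on the high fat array of BXD45 against a median of 7.77. The high fat array of BXD48 had the lowest median correlation with the other arrays, 0.978. Without BXD45, BXD48 and BXD96, a choice made after the data were seen, 9768 genes differed between the diets, 18 lists passed and 3275 genes differed among strains. The fibroblast markers, fatty acid synthesis and thymus and T cell markers then missed the test (adjusted p = 0.0617, 0.0961 and 0.0698), and complexes II to V and the tricarboxylic acid cycle passed it, with lower means (adjusted p = 0.0179 and 0.01).

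**Figure D4:**
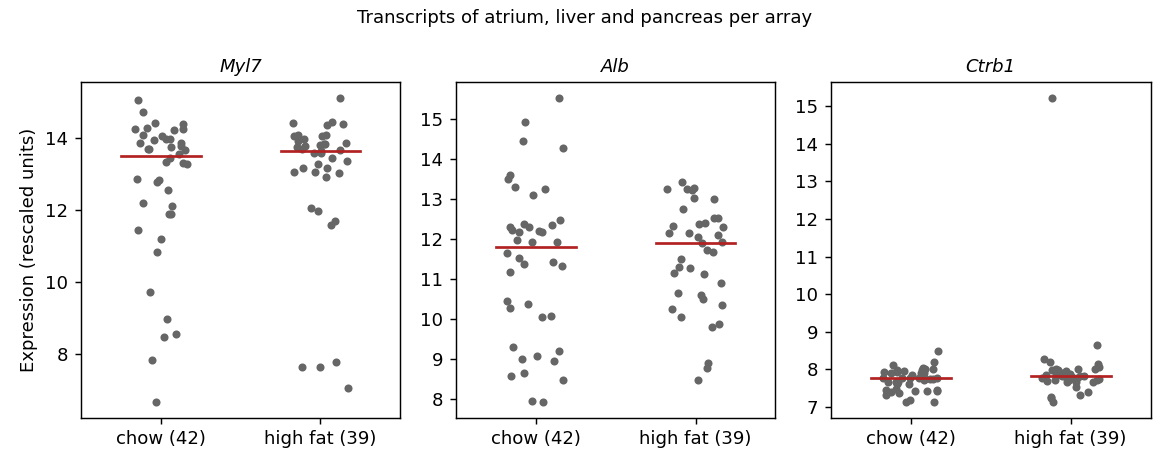
Expression in rescaled units (vertical axes) of Myl7, Alb and Ctrb1 on each of the 42 chow and 39 high fat arrays (grey points, spread horizontally), with red lines at the medians. One high fat array stands at 15.2 for Ctrb1, where the median of all arrays is 7.77.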

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

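Tests chosen after the results were seen are those on the ERCC probe sets, on the directions of genes by level, on random lists, on the sarcomere and complex I lists and on the fibroblast markers. The reassignment of diet labels and the tissue covariates were set out before their results were seen.

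A signal between the diets appeared in probe sets outside the genes reported on. Of 92 ERCC control probe sets 37 were called. Among probe sets that are not controls and are missing from the gene annotation, 4258 of 15820 were called (26.9%).

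The number of genes that differ between the diets was the first pattern weighed. Reassigning the diet labels within strains excluded chance, since 1 of 100 assignments (the real one, 9985 genes) gave as many and the highest of the others gave 1. The authors' rescaling moves genes of the same level on an array alike, so it is argued against as the whole cause by called genes that went both ways in every level decile, at least 34.6% of them in the rarer direction, while a part played by it stays open. A technical difference between the chow and the high fat arrays stays open for single genes, because 40.2% of the ERCC probe sets were called against 45.1% of genes of the same level. An effect of diet stays open beside it, and both may contribute.

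As to the second pattern, the fall of the branched chain list, shifts of single probe sets without regard to function are argued against by the upper bound of its 95% interval between strains, at percentile 0 of 10000 random lists matched on level, although camera's adjusted p with an estimated correlation was 0.40. The fall was larger than that of the sarcomere list, by -0.104 ± 0.112 (SD between strains) and in 34 of 39 strains (sign-flip permutation p = 1e-05, the smallest possible). This cannot decide on a lower share of cardiomyocytes as the whole cause. Lists that differ in level may fall unequally with the same loss of these cells, and the sarcomere genes are brighter and their range may be narrower. The sarcomere list fell too, with a mean of -0.0705. Complex I genes, also abundant in cardiomyocytes, gave a difference of -0.179, in 37 strains. The fall was thus not of equal size over these lists, which leaves the share of cardiomyocytes open. Atrial or liver tissue is argued against by a shift of -0.171 (95% interval -0.205 to -0.137) with both marker means as covariates. Diet stays open as a candidate explanation, as do a lower share of cardiomyocytes and a technical difference that acts on this list.

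The rise of the collagen list was the third pattern. The lower bound of its 95% interval between strains lay at percentile 99.9 of the random lists, against shifts of single probe sets without regard to function, although camera's adjusted p with an estimated correlation was 0.995, and the rise was 0.120 (95% interval 0.0708 to 0.169) with the tissue covariates. The rise was larger than that of 8 other fibroblast markers, by 0.0678 ± 0.101 (SD), in 28 of 39 strains (sign-flip permutation p = 0.00021). This cannot decide on a higher share of fibroblasts as the whole cause. Markers that differ in level, or that other cells share, may rise unequally with the same gain in fibroblasts. The 8 markers rose too, by 0.0618 (p = 0.022), so a part or all of the rise may come with fibroblast number. Diet stays open and was not tested apart from the arrays.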

How the results depend on the processing

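Alternatives added after the data were seen are the removal of 3 strains, the size of the control probe sets' differences and the tissue covariates. The number of genes that differ between the diets stayed between 8901 and 10306 under the other settings, and removing the strain block gave 8901 genes over the 78 paired arrays and 9074 over all 81. It was 4720 in genes above the median level, where fewer genes were tested, 6411 and 5664 in the strains at odd and at even places, where fewer strains entered, and 2012 when the difference had to exceed the 95th percentile of the ERCC probe sets. Leaving out 1 of the 4 parent arrays gave between 246 and 342 parent genes against 524. The number of lists that passed ran from 14 to 21 against 19, strain genes from 2772 to 4385 against 3285 and parent genes under the other settings from 506 to 558. Parent genes that vary among BXD numbered 396, with 463 and 398 in the alternatives. None of the relations of the PPAR list fixed beforehand passed after quantile normalization or with list medians. The relation of the branched chain and collagen shifts, described below, had r of -0.817 after quantile normalization. Of 45 lists 31 kept their call in every setting. The lung marker list reversed to -0.053 (adjusted p = 0.374) with members above the median gene level, and the cause was not tested. With all 81 arrays in place of the 78 paired ones and no strain block, 2 changes that were not tested apart for lists, the calls were lost for fatty acid synthesis, interferon response, skeletal muscle, fibroblast and T cell markers, and with each array centred on its median for fatty acid synthesis, chaperones, transcriptional regulators and T cell markers. Of 208 named or listed diet genes 136 kept their call in every setting, and none changed direction. A minimum fold, foreseen beforehand, was not applied, because the scale of the values is unknown. Dim genes have the larger errors, with a median SE of 0.0463 in the second level decile and 0.0268 in the highest.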

Other observations

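Among the tests here, those on neighbouring genes, on the relation of the branched chain and collagen shifts and on the pairing of arrays were set out before their results were seen, and those on probe mismatch, atrial markers, other lists related to the branched chain list, the relation within diets and pancreas or airway markers after.

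Several further gene groups differed between strains. The macrophage marker mean had an intraclass correlation of 0.494 between the 2 arrays of a strain (13 of 17 members called among strains), the fibroblast markers 0.540 (6 of 11), the immediate early genes 0.620 (15 of 21) and the muscle atrophy list 0.540 (5 of 14). Heat shock genes had 0.430, with 9 of 18 called (limma F test), and the oxidative stress list 0.427, with 13 of 20. Each list mean passed the permutation test over 45 lists, with adjusted p of 0.0072, 0.000643, 0.000643, 0.000643, 0.0142 and 0.0129 in that order. Most of the 45 lists passed it, so these groups are examples. Ketone body use (intraclass correlation 0.506) and sarcomere genes (0.436) had higher values than the heat shock list. Liver markers (0.407) and ribosomal proteins (0.319) passed as well.

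The fall of the branched chain list went with the rise of the collagen list across strains. Over 39 strains Pearson's r was -0.783 (permutation p = 1e-05, the smallest possible) and Spearman's rho -0.694 (p = 1e-05), and r was -0.732 without BXD61 and BXD63, the strains farthest from the median branched chain shift. The lists have no gene in common. It was the lowest r of the branched chain list with any of 44 other lists, and the macrophage, fibroblast and cardiac stress lists also had r below -0.5. Of the same lists, fatty acid oxidation, the tricarboxylic acid cycle and mitochondrial chaperones had r above 0.5, the last the highest at 0.697. The levels of both lists were related within each diet as well, with r of -0.611 over chow and -0.735 over high fat arrays, and r of the shifts was -0.729 with the atrial and liver marker differences removed. A balance of cell types, of mitochondrial transcripts or of array quality that differs between pools may therefore underlie the relation, whatever the diet.

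Neighbouring strain genes were compared across BXD strain means. The median absolute correlation of 2727 neighbouring pairs was 0.255, against a highest median of 0.148 in 1000 random sets of pairs from different chromosomes, and 69 pairs exceeded 0.8. Inheritance of shared segments may account for this, and overlapping probes of neighbouring genes were not tested. Pairing chow arrays with high fat arrays of other strains gave at most 2 strain genes in the 99 other pairings, so 1 of 100 gave as many as the real 3285 and chance is excluded.

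Probes designed on C57BL/6J sequence could lower the signal of DBA/2J transcripts, but 45.8% of the parent genes were higher in C57BL/6J (exact binomial 95% interval 41.5% to 50.2%, p = 0.0602), which gives no excess in that direction. Single genes may still be affected.

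The level of atrial transcripts may follow the dissection of each pool more than the strain, as the atrial list had an intraclass correlation of 0.151 between the 2 arrays of a strain (permutation p = 0.179), a test that leaves a part of the strain open. Of 9 liver markers 8 were highest on the chow array of BXD96. On the high fat array of BXD45 15 of 15 measured exocrine pancreas markers were highest, including 8 of 8 that had not been looked at when the list was written, and 3 of 9 airway markers. Ucp1, a brown fat gene chosen after its values were seen, reached 11.1 on the chow array of BXD90 against a median of 7.31.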
